A study of Mus musculus with 9 samples.

How the data were processed

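RNA sequencing of mouse kidney (2 libraries) and muscle (7 libraries) was analysed from 1 table per library, 9 in all, each with 24421 gene symbols. The deposited tables give raw read counts per gene, which the authors did not normalise, and a second column with RPKM, which the authors computed from the same counts. Per the submitters' processing notes the reads were aligned with HISAT2 2.1.0 to the mouse genome build mm10. The counting program, the annotation, the strand setting and the treatment of reads with several positions are not given in the sources used here. RPKM recomputed from the counts and gene lengths was within 0.0005% of the deposited value for genes with 100 or more counts, and RPKM served only for this check. No mitochondrially encoded gene is in the tables, which left 1 of the gene lists without a measured member. Among genes with 100 or more reads over the 9 libraries, counts were the same in every library for 53 genes in 24 groups, such as near-identical gene copies, and each group entered gene lists at most once. The beta-globin genes, which have such copies, were left out of the counts and medians of the erythroid list.

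Groups followed the labels: 8 groups with 1 library each except wild type PBS muscle with 2. The number given to the wild type libraries sets no order, and set letters come from the names of the tables. No paired analysis was possible because the labels link no library to another from the same animal. The muscle comparisons that use wild type PBS share those 2 libraries. Set letter and group cannot be told apart for groups found in 1 set only, and changes against the wild type library of the same set are therefore given beside the means. The comparisons, tests, gene lists, rule for named genes and most alternatives were fixed before the data were examined.

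Counts were scaled with TMM, and CPM and log2 CPM with a prior count of 2 were computed with edgeR 4.0.16 in R 4.3.3. In muscle, edgeR's quasi-likelihood test was fitted to all 7 libraries with 1 coefficient per group, after filterByExpr with a minimum count of 10, which kept 15482 genes, and p values were adjusted by the Benjamini-Hochberg method. The wild type pair gives the fit its 1 residual degree of freedom, so single libraries are assumed to vary like that pair, and empirical Bayes added 15.2 prior degrees of freedom. In kidney, with 1 library per group, no test was made, and 15986 genes were described by their log2 ratio. Ratios of kidney CPM, and of muscle CPM where they are given with an interval, have exact conditional binomial 95% intervals. Intervals and floors cover counting error only. A value of 0 counts was set to a limit of 3 counts in that library for a fold, which is then written as at least that fold.

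Because the test called 0 genes in each muscle comparison, the size rule planned for kidney took its place: a change of 2-fold or more and 100 or more counts in the higher library, in muscle against each wild type library where wild type PBS was the reference. Genes were named under 3 rules. The first took the 10 highest and 10 lowest log2 changes past the size rule, without predicted genes, RIKEN clones, pseudogenes, microRNAs and small nucleolar RNAs. The second took up to 2 members in each direction with the largest change from each list described, and the third took a panel of Arrb1, Arrb2, Lrp5, Lrp6, Kremen1, Ckap4, Dkk1, Axin2, Fbxo32 and Trim63. Further genes, such as Cish in tumour muscle, Arc beside the immediate early list and the genes shared by kidney and muscle, were chosen after their values were seen.

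The 35 gene lists and 15 cell marker lists each gave a median log2 change and its percentile among 10000 random lists matched for expression in 20 bins. Values for the list of sex-linked genes are not given. A list was described by name with 3 or more members, or 20% of them, past the size rule, or a percentile under 2.5 or over 97.5. The percentile compares a list with other genes of the same libraries and does not count differences between animals. Expected counts under no change came from 50 simulations with the fitted spread, for every muscle comparison except the interaction. That spread comes from a wild type pair with 1 library in set B and 1 in set C, and it therefore includes any difference between those sets. Gene positions are from the mouse build GRCm38 annotation.

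The methods were tested on simulated data with 15482 genes. At the fitted spread, with a biological coefficient of variation of 0.498, edgeR recovered 9 of 67 genes changed 4-fold, 57 of 67 changed 16-fold and 64 of 66 changed 64-fold, and called 13 unchanged genes. The size rule recovered 52 of 67, 63 of 67 and 60 of 66, and counted 1146 unchanged genes. With a coefficient of 0.2, edgeR recovered 100% at each fold and called 11 unchanged genes. In simulated kidney counts the size rule recovered 200 of 200 genes changed 4-fold and counted 0 unchanged genes, and a list of 20 shifted genes reached percentile 100 against 77.0 for an unshifted one.

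Alternatives were DESeq2 size factors, total counts, DESeq2 1.42.0, limma-voom (limma 3.58.1), robust empirical Bayes, no filter, a mean of 50 counts, all 9 libraries in the fit, other count minimums and prior counts, and leaving out each wild type muscle library. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.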

Results

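RNA sequencing measured gene expression in 9 mouse libraries, 2 from kidney and 7 from muscle. Kidney was represented by 1 library from a tumour-bearing animal and 1 from a wild type animal, both given PBS. In muscle, 2 wild type PBS libraries were compared with 1 library each of tumour PBS, tumour MDC, wild type DKK1, beta-arrestin knockout PBS and beta-arrestin knockout DKK1. DKK1 is a secreted Wnt inhibitor that binds the co-receptors LRP5 and LRP6, and beta-arrestins are adaptor proteins that draw receptors into the cell. The labels name MDC by these letters alone, and they do not say which tumour was used or which of the beta-arrestin genes was deleted. The series title gives the subject as LRP6 uptake driven by Dkk1 in cancer cachexia, the wasting that accompanies a tumour.

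Total counts were 44421797 (tumour) and 42480786 (wild type) in kidney and from 21358854 to 32607835 per library in muscle. A count of 0 allowed up to 3 counts, which after TMM scaling is from 0.0673 CPM (tumour kidney) to 0.141 CPM (wild type muscle library 1). Set letters in the table names put the kidney pair in set A, both tumour muscle libraries and wild type library 1 in set B, and the DKK1 libraries, the libraries labelled knockout and wild type library 2 in set C. Expression is given as CPM after TMM scaling, with the mean ± SD of the wild type pair (n = 2), and 1 library in every other group has no replicate check. A log2 change against wild type PBS muscle is the mean of the changes against library 1 and library 2, and those 2 values follow in that order where they are given.

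The 2 wild type PBS muscle libraries differed widely in fibre type, immune, fat and matrix genes. Slow fibre genes were at least 2-fold higher in library 2 for 15 of 16 members, with a median log2 difference of 5.03, and Tnni1, the slow-fibre troponin I, was at 29.5 CPM against 0.0937 CPM. Csrp3, a stretch-sensing protein of the Z-disc, was at 105 CPM against 0.234 CPM and led the genes higher in library 2, with Gpnmb, Bdh1, Ankrd2, Chil3, Adam12, Myh6, Fgfbp1 and Dach2 also in the top 10. Adipocyte markers were higher for 13 of 16 genes (median 2.67), macrophage and monocyte markers for 18 of 26 (2.48) and extracellular matrix genes for 24 of 31 (1.59). Ribosomal protein genes were lower for 26 of 35 members (-1.24) and fast fibre genes for 11 of 18 (-1.22). Interferon response genes were lower for 14 of 33 members (-0.95), with the GTPase gene Igtp at 17.4 CPM against 503 CPM. Gbp2b, another interferon-induced GTPase, had 0 counts in library 2 and was at least 267-fold lower there, followed by Tmem232, Plet1os, Habp2, Miox, Pigr, Ostn, S100a9 and Srrm4os. Unlike Igtp, Gbp2b followed the set letter, with 5 counts or fewer in each library of set C.

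By size, 1529 genes were higher and 1297 lower in library 2, of 10701 with 100 or more counts. Scaling by total counts alone gave 2636 and 546 and moved the median log2 of all genes from -0.07 to 0.37. Across genes the pair correlated at r = 0.910, below the median of 0.958 for 9 pairs of muscle libraries within a set and 0.935 for 12 pairs across sets. The common biological coefficient of variation, which rests on this pair alone, was 0.498.

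Neither beta-arrestin gene was lower in the libraries labelled knockout. Arrb1, which encodes beta-arrestin-1 (mm10 chromosome 7, 99535466 to 99606771), was at 20.5 CPM in the library labelled knockout PBS and 28.2 CPM in the library labelled knockout DKK1, against 18.8 ± 2.12 CPM in wild type PBS and 22.1 CPM in wild type DKK1. Arrb2, which encodes beta-arrestin-2 (chromosome 11, 70432635 to 70440828), was at 9.61 and 7.98 CPM in those libraries, against 7.72 ± 0.186 CPM in wild type PBS and 8.32 CPM in wild type DKK1. In the tumour PBS and MDC libraries Arrb1 was at 19.9 and 18.9 CPM and Arrb2 at 13.7 and 16.4 CPM. Counts summed over a whole gene do not show the loss of a single exon.

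**Figure D1:**
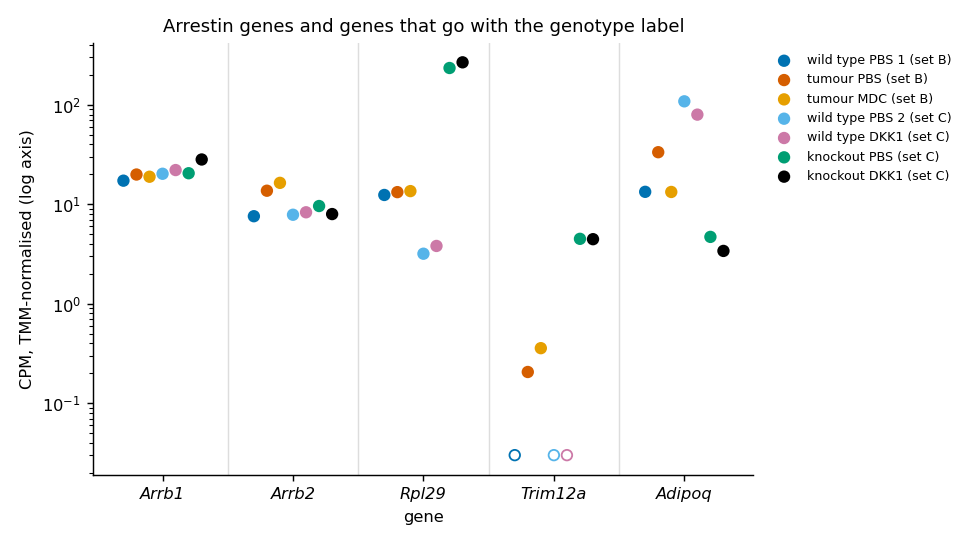
CPM (log axis) of Arrb1, Arrb2, Rpl29, Trim12a and Adipoq in the 7 muscle libraries, 1 point per library, with open points at the bottom for 0 counts. Arrb1 lies between 17.3 and 28.2 CPM in all 7, while Rpl29 is at 235 and 268 CPM in the libraries labelled knockout and at 13.6 CPM or less in the other 5.

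The tumour comparison asks what a tumour elsewhere in the body changes in muscle. Neutrophil genes were higher in tumour PBS muscle than in either wild type library. S100a9, a calcium-binding protein of neutrophil cytoplasm (chromosome 3, 90692632 to 90695721), was at 164 CPM against 3.79 ± 5.05 CPM in wild type, and its partner S100a8 was at 76.0 CPM against 1.72 ± 2.07 CPM. The granule genes Ngp and Ltf, the neutrophil resistin-like gene Retnlg and the chemokine receptor gene Cxcr2 were also among the 10 highest, at log2 changes of 6.18 to 6.78. Of 17 neutrophil markers measured, 13 were at least 2-fold higher against each wild type library. Their median log2 change was 4.59, or 4.16 with the 3 markers at 0 in both wild type libraries set to the bound that 3 counts give. The wild type pair differed by a median of 0.00, but 5 markers in library 1 and 8 in library 2 had 0 counts. S100a9 was at 7.36 and 0.218 CPM in libraries 1 and 2, and S100a8 at 3.19 and 0.262 CPM.

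Cxcl13, a chemokine that draws B cells (chromosome 5, 95956951 to 95961068), was at 30.2 CPM against 0.228 ± 0.0754 CPM. Chil1, a secreted chitinase-like protein, had 180 counts and 0 in both wild type libraries, at least 39.0-fold higher. The pancreatic amylase genes Amy2a5 and Amy2a2, the latter sharing its counts with near-identical copies, were at least 108-fold and 75.6-fold higher than the same limit. Among IL-6/STAT3 and acute phase genes, 7 of 25 were higher (median 0.93; 1.42 and 0.72), led by the siderophore-binding gene Lcn2 at 20.6 CPM against 1.80 ± 2.08 CPM and the NF-kappa-B cofactor Bcl3 at 8.56 CPM against 1.69 ± 0.0744 CPM. Metal-binding Mt2 was at 134 CPM against 16.6 ± 16 CPM and Mt1 at 164 CPM against 34.1 ± 20.4 CPM, and the transcription factor gene Cebpd was at 126 CPM against 34.3 ± 10.1 CPM. Mt1, Mt2 and Cebpd were the 3 of 20 members of the atrophy ligase and FoxO target list past the size rule (median 0.21, 0.37 and 0.11), and Mt1, Mt2 and Chac1 the 3 of 23 of the iron, glutathione and NRF2 list (-0.03, -0.10 and -0.11). The muscle ubiquitin ligase genes themselves stayed within the wild type spread: Fbxo32 was at 314 CPM against 281 ± 91.7 CPM and Trim63 at 191 CPM against 183 ± 90.3 CPM.

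Erythroid markers were higher for 3 of 8 members (median 1.99; 1.96 and 1.98), with the haem synthesis gene Alas2 at 15.6 CPM against 3.76 ± 1.54 CPM. Beta-globin Hbb-bt, which shares counts with a copy and is not among those 8, was at 291 CPM against 68.3 ± 17.1 CPM. Endothelial markers were higher for 3 of 19 (0.51, 0.94 and 0.27), among them the vessel-wall genes Plvap, 68.5 CPM against 18.0 ± 2.99 CPM, and Ly6c1, 248 CPM against 105 ± 8.01 CPM. Single members of other lists were the fatty acid elongase Elovl6 (log2 3.12), the monocyte gene Ly6c2 (2.39), the secreted IGF-binding Igfbp7 (1.25), the death effector Bbc3 (1.23) and the pericyte gene Higd1b (1.08). Actc1, the cardiac form of actin, was lower at 32.0 CPM against 312 ± 132 CPM, the interferon-induced chemokine Cxcl9 at 0.5 CPM against 7.15 ± 1.42 CPM and the antiviral gene Ifit3 at 6.03 CPM against 15.8 ± 4.79 CPM. Rmrp, Rpph1, Lars2, Rn45s, Hsd3b4, Spp1, Atcay and Cyp26b1 made up the rest of the 10 lowest, at log2 changes of -4.10 to -2.39. Among the 7 muscle libraries the RNA genes Rmrp, Rpph1 and Rn45s and the Lars2 gene were each highest in wild type library 2 and lowest in knockout PBS, and Rn45s alone held from 0.359% to 8.29% of a library's counts. Other lists outside the central 95% of matched random lists with 1 sign against both wild type libraries were ribosomal proteins (0.82, 0.17 and 1.41), lymphocyte markers (1.24, 0.95 and 1.20), cell death and p53 targets (0.40, 0.44 and 0.17), fibroblast markers (0.22, 0.49 and 0.04), sarcomere structure (-0.24, -0.19 and -0.23) and liver markers (-0.59, -0.49 and -1.20). For 16 of the 29 lists described, slow fibre genes (3.88 and -1.43) and macrophage markers (1.48 and -0.55) among them, the 2 wild type libraries gave medians of opposite sign. These also took in glucocorticoid, interferon, heat shock, myogenic, oxidative phosphorylation, glycolysis, lipid synthesis, matrix, cell cycle, proximal tubule, kidney injury, pericyte, Schwann and cardiac genes. The 20 further lists had neither 3 members past the size rule nor an outlying median.

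edgeR's quasi-likelihood test called 0 of 15482 genes at a Benjamini-Hochberg adjusted p under 0.05, with 165 genes at an unadjusted p under 0.05. The smallest adjusted p was 0.0577, for Cxcl13. DESeq2 called 8 genes higher and 4 lower and limma-voom 0, and 15 neutrophil markers passed edgeR's test when adjusted over the list alone, as did 3 atrophy and FoxO, 2 iron and NRF2 and 1 of the cardiac genes over theirs. By size, 144 genes were higher and 56 lower against each wild type library. Without wild type library 1 these counts were 918 and 821, and without library 2 they were 938 and 260. Unchanged libraries simulated with the fitted spread gave a mean of 545 higher and 606 lower, so the counts lay below what that spread alone produces.

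**Figure D2:**
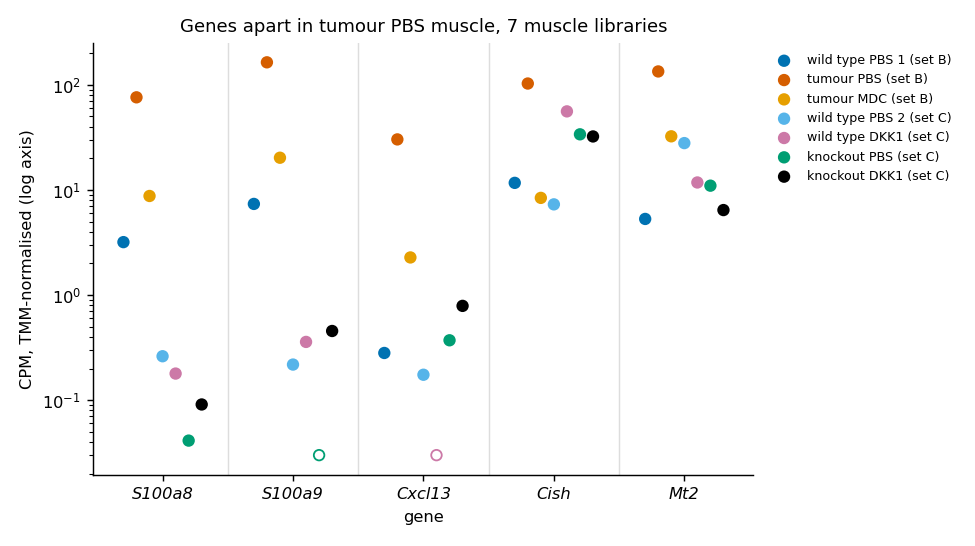
CPM (log axis) of S100a8, S100a9, Cxcl13, Cish and Mt2 in the 7 muscle libraries, 1 point per library, with open points at the bottom for 0 counts. The tumour PBS library is highest for each gene, with S100a9 at 164 CPM there, 20.2 CPM under MDC and 7.36 CPM or less elsewhere.

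MDC was set against PBS in tumour-bearing animals, both in set B. Neutrophil, macrophage, fat and lipid synthesis genes were lower in the MDC library and slow fibre genes were higher. The 2 wild type libraries, in different sets, differed in these lists by medians of 0.00, 2.48, 2.67, 0.91 and 5.03 in that order. Those differences exceeded the ones between MDC and PBS in all but the neutrophil list. Cish, a feedback inhibitor of cytokine receptor signalling (chromosome 9, 107296026 to 107302784), was at 8.40 CPM under MDC and 103 CPM under PBS, beside 11.7 and 7.29 CPM in the wild type libraries. Cxcl13 was at 2.28 CPM against 30.2 CPM, and Chil1 had 1 count against 180, a ratio of 118 (95% counting interval 21.0 to 4705). Of 17 neutrophil markers 13 were at least 2-fold lower (median -2.63, or -2.56 with the member at 0 set to its bound), including Ltf at 1.03 CPM against 12.9 CPM and Retnlg at 1.74 CPM against 19.5 CPM. Macrophage and monocyte markers were lower for 9 of 26 (-0.79), with the Fc receptor genes Fcgr1 and Fcer1g leading.

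Adipocyte markers were lower for 9 of 16 members (-1.27), with the fat hormone gene Retn at 5.58 CPM against 22.9 CPM and the lipid droplet gene Cidea at 0.357 CPM against 4.23 CPM. Lipid and sterol synthesis genes were lower for 9 of 25 (-0.58), with fatty acid synthase Fasn at 42.0 CPM against 168 CPM and Elovl6 at 1.70 CPM against 13.8 CPM. Slow fibre genes were higher for 12 of 16 (1.87), with the slow myosin heavy chain Myh7 (chromosome 14, 54970684 to 54994626) at 332 CPM against 34.1 CPM and the troponins Tnni1 and Tnnc1 at 85.3 and 126 CPM against 9.32 and 14.0 CPM. Mt2 was at 32.3 CPM against 134 CPM, Pdk4, a kinase that blocks pyruvate use, at 208 CPM against 654 CPM, and Foxo3 at 1.25 CPM against 3.68 CPM. Fbxo32 was at 609 CPM against 314 CPM, Trim63 at 205 CPM against 191 CPM, and the Wnt target Axin2 at 2.14 CPM against 4.97 CPM.

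Further lists with members lower were IL-6/STAT3 and acute phase (4 of 25, -0.48; Lcn2, Hp), atrophy ligases and FoxO targets (3 of 20, -0.25; Mt2, Foxo3), iron and NRF2 genes (3 of 23, Chac1 among them; 0.04), fatty acid oxidation (3 of 32, -0.06), podocyte genes (3 of 9, -0.21; Plat), immediate early genes (2 of 23, -0.46; Fos, Btg2), kidney injury genes (2 of 25, -0.54; C3) and endothelial markers (2 of 19, -0.27; Kdr, Vwf). Denervation genes went both ways, with Sln higher and Runx1 and Ache lower, cardiac markers had 2 of 9 higher (0.22; Actc1) and liver markers 2 of 16 higher (1.54; Serpina1a, Alb). Outlying medians with at most 1 member past the size rule were proteasome subunits (0.32), fast fibre genes (0.41), oxidative phosphorylation (0.26), circadian clock (0.25; Per3), tendon and cartilage (0.70; Comp), skeletal muscle markers (0.46), cell cycle (-0.60; Mcm5), extracellular matrix (-0.32; Postn), fibroblast (-0.23; Fbln1), pericyte (-0.35; Rgs5), glucocorticoid-responsive (-0.25) and polyamine genes (-0.14). Mhrt, Rpph1, Rmrp, Myh6, Lars2, Tnnt1 and Igfn1 completed the 10 highest and Tmem45b, Mrgpra2b, Stc1 and Cd177 the 10 lowest. edgeR's quasi-likelihood test called 0 of 15482 genes, with 38 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. By size, 129 genes were higher and 350 lower, where unchanged libraries simulated with the fitted spread gave means of 1409 and 1565. That spread comes from a wild type pair in different sets (r = 0.910), while the MDC and tumour PBS libraries are both in set B (r = 0.971).

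Set against wild type PBS, erythroid markers were higher in the MDC muscle library. Alpha-globin Hba-a1 was at 2548 CPM against 324 ± 5.70 CPM, and erythroid markers were higher for 3 of 8 members (median 2.58; 2.79 and 2.48), with 3 passing edgeR's test when adjusted over the list alone. So did 2 immediate early, 1 adipocyte and 1 kidney injury gene over their lists. Slow fibre genes were higher for 6 of 16, but the median of 2.95 came from 5.92 against wild type library 1 and 0.14 against library 2. Sln, which inhibits the calcium pump, was at 33.5 CPM against 2.20 ± 3.12 CPM, and the endothelial BMP-pathway gene Tmem100 was at 137 CPM against 17.7 ± 12.8 CPM. Neutrophil markers remained higher for 2 of 17, S100a9 at 20.2 CPM and S100a8 at 8.76 CPM, with a median of 2.59 (1.86 and 2.59) that became 1.72 with the 4 members at 0 set to their bound.

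Fosb and Fos, immediate early transcription factors, were at 0.134 CPM against 8.46 ± 3.15 CPM and 6.48 CPM against 55 ± 29.5 CPM, and with Egr1 they made 3 of 23 immediate early genes lower (-0.16, -0.25 and -0.75). Arc, a neuronal activity gene outside that list, had 2 counts against 28 and 270. The polyamine genes Amd1, 340 CPM against 1489 ± 260 CPM, and Smox, 102 CPM against 444 ± 110 CPM, were lower (3 of 15, -0.04, -0.16 and 0.17). Cxcl9, Nnat, Spp1, Cidea, Shroom4, Lrtm2, Pdpr and Slc15a5, the last with 0 counts against 4 and 229, completed the 10 lowest with Fosb and Arc, and Tnni1, Mhrt, Tnnc1, Myh6, Myl2, Tnnt1 and Myh7 the 10 highest. IL-6/STAT3 genes were higher for 3 of 25 (0.38, 1.08 and 0.00; Bcl3, Lbp) and endothelial markers for 3 of 19 (0.24, 0.61 and -0.01; Cldn5, Plvap). Denervation genes went both ways (Myh3 higher, Ache lower; -0.36, 0.15 and -0.54). Arrb2 was higher at 16.4 CPM against 7.72 ± 0.186 CPM, a log2 change of 1.08, and was the 1 member past the size rule among Wnt receptors, Dkk1 partners and arrestins. Adipocyte markers were lower for 2 of 16 (-0.72; 0.23 and -2.20; Pck1), and cardiac markers had Actc1 lower and 1 member higher (-1.35, 0.00 and -1.31; -0.70 with 1 member at its bound). Outlying medians with 1 sign against both libraries were ribosomal proteins (0.95, 0.32 and 1.62), tendon (1.11, 0.75 and 1.26; Scx), liver (0.73, 0.71 and 0.35), atrophy (0.38, 0.52 and 0.27) and proteasome genes (0.32, 0.02 and 0.54). Those below 0 were fatty acid oxidation (-0.37, -0.04 and -0.70), lipid synthesis (-0.35, -0.14 and -0.81; Gpam), cell cycle (-0.74, -0.20 and -1.43) and proximal tubule genes (-0.82, -2.35 and -0.03). For 10 of 25 lists described, among them IL-6/STAT3, interferon, denervation, glycolysis, matrix, polyamine, adipocyte, macrophage, endothelial and pericyte genes, the signs were opposite. edgeR's quasi-likelihood test called 0 of 15482 genes, with 231 at an unadjusted p under 0.05, while DESeq2 called 6 higher and 5 lower and limma-voom 0. By size 76 genes were higher and 89 lower, against simulated means of 479 and 610. These counts were 1229 and 1249 without wild type library 1 and 343 and 240 without library 2.

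The share of tumour genes that lay nearer wild type under MDC was counted over the 200 genes that passed the size rule for the tumour, since the test called none. In the MDC library 68 of these, or 34%, had moved back by at least the midpoint of the tumour change, 52 of 144 higher genes and 16 of 56 lower ones. A simulated MDC library with tumour PBS means gave 12.6% (7 to 18.5%) and one with wild type means gave 90.8% (84.0 to 96.0%). Both simulations took the observed tumour PBS values of the selected genes as exact. They therefore do not show how many genes selected for a large change would move back without MDC, and the share cannot be credited to MDC. Against wild type library 1 alone the share was 31.0%. Over the tumour genes called by DESeq2 it was 60.0% (6 of 10), and 3 of those 6, Lars2, Rmrp and Rn45s, were also highest in wild type library 2 and lowest in knockout PBS among the muscle libraries.

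DKK1 was given to wild type mice to see what the protein changes in muscle without a tumour. The medians of the Schwann cell, endothelial and matrix lists were above 0 against both wild type libraries, and those of fast fibre genes and skeletal muscle markers were below 0. The wild type pair itself differed by medians of 2.23, 0.71 and 1.59 in the lists above 0 and by -1.22 and -0.66 in those below. The myelin-supporting gene Prx was at 37.2 CPM against 8.29 ± 9.20 CPM. Schwann cell and nerve markers were higher for 7 of 14 members (median 2.21; 3.43 and 1.04). Matrix genes were higher for 5 of 31 (1.34; 2.1 and 0.50), with collagens Col15a1 at 74.6 CPM against 21.6 ± 6.26 CPM and Col6a2 at 152 CPM against 51.3 ± 31.4 CPM. The vascular receptor Kdr was at 157 CPM against 50.5 ± 25 CPM and the endothelial phosphatase Ptprb at 284 CPM against 95.9 ± 58.9 CPM (4 of 19, 1.20; 1.55 and 0.91).

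Among Wnt targets, the secreted Wnt inhibitor Sfrp5 was at 19.1 CPM against 3.37 ± 3.31 CPM, the feedback inhibitor Nkd1 at 6.29 CPM against 1.81 ± 1.70 CPM and Dkk3 at 30.9 CPM against 121 ± 53.3 CPM (2 of 20 higher, 1 lower; 0.56, 0.64 and 0.38). Axin2 was at 9.98 CPM against 6.12 ± 2.63 CPM. Lrp6 was at 61.2 CPM against 47.0 ± 17.5 CPM, Lrp5 at 41.3 CPM against 19.0 ± 18.3 CPM and the DKK1 receptor gene Kremen1 at 90.8 CPM against 71.9 ± 42.4 CPM, while Dkk1 itself had 0 counts in every muscle library except MDC, with 6. The list of Wnt receptors, Dkk1 partners and arrestins had a median of 0.40 (0.39 and 0.14) and no member past the size rule. The atrophy ligase gene Fbxo32 passed the size rule as lower, at 93.4 CPM against 281 ± 91.7 CPM, and Trim63 was at 121 CPM against 183 ± 90.3 CPM. Nr4a3, an orphan nuclear receptor induced by activity, was at 12.9 CPM against 1.25 ± 0.448 CPM and Klf4 at 106 CPM against 20.7 ± 14.1 CPM (3 of 23 immediate early genes, 0.27; 0.67 and -0.13), a list in which 2 passed edgeR's test when adjusted over the list alone.

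Myostatin, activin and TGF-beta signalling genes were higher for 4 of 24 (0.63, 1.21 and 0.45; Id1, Fst). Erythroid markers were higher for 3 of 8 (1.32, 1.18 and 1.24; Alas2, Hba-a1) and fibroblast markers for 3 of 18 (1.19, 1.52 and 0.77; Lum, Dcn). Heat shock genes were higher for 2 of 15 (0.68, 1.39 and 0.14; Hspa1b, Dnaja1), lipid synthesis for 2 of 25 (0.82, 1.27 and 0.21; Elovl6, Acly) and myogenic genes for 2 of 21 (0.60, 0.56 and -0.11; Hey1). A single member each was higher among insulin/IGF (0.29, 0.27 and 0.20; Igf1), pericyte (1.48, 2.27 and 0.63; Rgs5), podocyte (0.55, 1.17 and 0.25; Podxl), slow fibre (2.67; 5.26 and 0.10), skin (0.48, 0.67 and 0.15; Sfn) and tendon genes (0.72, 0.39 and 0.58; Tnmd higher, Scx lower). Fast fibre genes had a median of -1.0 (-1.76 and -0.30, 1 of 18 lower) with Myh4, the fastest myosin, at 12656 CPM against 51048 ± 33415 CPM, and skeletal muscle markers -1.05 (-1.40 and -0.36, 2 of 15 lower), with the giant spring protein Ttn at 2325 CPM against 10705 ± 6261 CPM. Proximal tubule genes (2 of 30 lower, -2.04, -2.94 and -0.61; Dpep1 higher) and Kap, Slc34a1 and Slc27a2 among the 10 lowest are kidney genes, and wild type library 1 held most of their counts, with 1123 for Kap against 90 in library 2. The other genes in the lowest 10 were Habp2, with 0 counts against 571 and 5, Serpina3g, Eno1b, Rmrp, Lars2, Rn45s and Rpph1. The highest 10 were H2-Q10, Rab6b, Lgi1, Hspa1b, Ddn, Myl3, Adra2c, Sorcs1, Duxbl2 and Fzd3, at log2 changes of 3.51 to 4.07.

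Outlying medians of the same sign against both libraries, with no member past the size rule, were proteasome (-0.41, -0.70 and -0.09), glycolysis (-0.60, -0.87 and -0.29), ribosomal (-0.73, -1.28 and -0.05), loop of Henle (-0.87, -1.44 and -0.30) and liver genes (-0.76, -0.58 and -0.73). Neutrophil markers had a median of -0.51 for the mean change but of 0.00 against each wild type library. The 6 of 31 lists whose sign differed between the wild type libraries were the adipocyte (0.80, 1.88 and -0.46), myogenic (0.60), glucocorticoid-responsive (0.40, 0.70 and -0.21), immediate early (0.27), fatty acid oxidation (0.22, 0.44 and -0.04) and interferon genes (-0.18, -0.44 and 0.45). edgeR's quasi-likelihood test called 0 of 15482 genes, with 206 at an unadjusted p under 0.05, while DESeq2 called 4 lower and limma-voom 0. By size, 264 genes were higher and 37 lower, against simulated means of 559 and 601. They numbered 342 and 124 without wild type library 1 and 2442 and 1280 without library 2.

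Tumour and DKK1 changes in muscle correlated at r = 0.173 across 15454 genes, which are not independent replicates, with a covariance of 0.110. Both changes share the wild type libraries, and unchanged libraries simulated against the same pair gave r = 0.344 (0.319 to 0.360) and a covariance of 0.293. With each change taken against the wild type library of its own set, so that none is shared, r was 0.108 and the covariance 0.0682. By size 24 genes were higher in both, where independent lists would give 2.46 and the simulation 118. Another 7 were lower in both, where these values were 0.134 and 102. The values for independent lists count all 15454 genes, also those with too few counts to pass the size rule, and so lie too low. Tumour PBS is in set B and wild type DKK1 in set C, while the simulation treated any set difference as random spread. The simulated values therefore cannot decide whether the tumour and DKK1 changes are shared.

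Comparing the library labelled knockout with wild type, both given PBS, gives the baseline for DKK1 in the libraries labelled knockout. The library labelled knockout PBS had less fat cell transcript and more of Trim12a and Rpl29. The catecholamine receptor gene Adrb3 (chromosome 8, 27225776 to 27250616) had 0 counts against 26 and 176. Cidec, which coats lipid droplets, was at 2.72 CPM against 78.9 ± 91.5 CPM, its partner Plin1 at 0.866 CPM against 24.7 ± 29.5 CPM and the glyceroneogenic enzyme gene Pck1 at 3.59 CPM against 72.9 ± 76.5 CPM. Adipocyte markers were lower for 7 of 16 (median -2.55; -1.20 and -4.30), and 8 passed edgeR's test when adjusted over the list alone, as did 2 neutrophil, 1 liver and 1 proximal tubule gene over theirs. Trim12a (chromosome 7, 104299894 to 104315466), of the antiviral tripartite-motif family, had 109 counts and 0 in both wild type libraries, at least 33.1-fold higher. Rpl29, a ribosomal protein gene (chromosome 9, 106429454 to 106431568), was at 235 CPM against 7.80 ± 6.53 CPM, and the orphan receptor gene Gpr75 at 4.13 CPM against 0.231 ± 0.203 CPM.

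Fgfbp1, Rab6b, Nxpe4, Utp14b, Cd28, Unc5a and Ms4a4c completed the 10 highest, and Rpph1, Mrap, Gdpd3, Rmrp, Arxes2, Serpina3g and Arxes1 the 10 lowest. Interferon response genes were lower for 3 of 33 (-0.85; -1.08 and -0.40; Cxcl9, Ifi27l2a), with Angptl4 and Ier2 lower in the lists of fatty acid oxidation (-0.40, -0.19 and -0.61) and immediate early genes (-0.46, 0.06 and -0.79). Medians of 1 sign against both libraries were also outlying for IL-6/STAT3 (-0.98, -0.39 and -1.37), proximal tubule (-1.39, -2.68 and -0.40), endothelial (-0.46, -0.14 and -0.79), fibroblast (-0.52, -0.20 and -0.79) and neutrophil genes (-1.15, -1.21 and -0.07, or -0.60 with 10 members at their bound). The kidney gene Kap had 1123 counts in wild type library 1, 90 in library 2 and 79 in the library labelled knockout PBS. Signs were opposite for 7 of 16 lists described, the glucocorticoid, immediate early, oxidative phosphorylation, matrix, ribosomal, loop of Henle and macrophage lists. Lrp6 was at 59.7 CPM, Axin2 at 6.31 CPM, Fbxo32 at 341 CPM and Trim63 at 219 CPM, each within 1 SD of the wild type mean. edgeR's quasi-likelihood test called 0 of 15482 genes, with 182 at an unadjusted p under 0.05 and a smallest adjusted p of 0.127, while DESeq2 called 4 higher and 15 lower and limma-voom 0. By size 78 genes were higher and 96 lower, against simulated means of 490 and 601. Their numbers were 331 and 718 without wild type library 1 and 854 and 701 without library 2.

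DKK1 against PBS in the libraries labelled knockout asks whether the response needs beta-arrestin. Slow fibre genes were higher under DKK1 for 15 of 16 members (median 3.64), and 8 passed edgeR's test when adjusted over the list alone. The 2 wild type PBS libraries differed by more in this list, by a median of 5.03, also with 15 of 16 members past 2-fold. Myh7 was at 2054 CPM against 8.37 CPM, the slow and cardiac troponin C gene Tnnc1 at 294 CPM against 2.35 CPM, Tnni1 at 240 CPM against 2.68 CPM and Tnnt1 at 493 CPM against 5.78 CPM. Macrophage markers were lower for 9 of 26 members and higher for 1, Cd163 (-0.64), with the pore-forming Mpeg1 at 8.07 CPM against 46.2 CPM and the Fc receptor Fcgr1 at 0.485 CPM against 4.79 CPM. Gpnmb, a lysosomal glycoprotein, was at 2.70 CPM against 25.8 CPM. Spp1, the matrix cytokine osteopontin, was at 3.52 CPM against 31.6 CPM.

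Fibroblast markers were higher for 5 of 18 (0.78; Fbln1, Pi16), and the secreted Wnt modulator Dkk2 was at 7.98 CPM against 1.28 CPM (1 of 20 Wnt targets, 0.43). Immediate early genes were higher for 4 of 23 and lower for 1 (0.67; Fos, Zfp36), erythroid markers higher for 3 of 8 (0.24; Alas2, Hba-a2), IL-6/STAT3 genes for 3 of 25 (-0.11; Lbp, C3), tendon genes for 2 of 12 (0.63; Comp, Prg4), atrophy genes for 2 of 20 (0.16; Ddit4, Cebpb), kidney injury genes for 2 of 25 with 1 lower (-0.20; Sox9 higher, Spp1 lower), cardiac markers for 2 of 9 (0.24; Tnnt2), and matrix genes (0.28; Fn1 and Ctgf higher, Postn lower) and sarcomere genes (-0.04; Myom3 and Lmod2 higher, Xirp2 lower) went both ways. Cell cycle genes had a median of -1.06 (Ccna2), liver markers -1.22, fast fibre genes -0.40 (Myh2 higher), skeletal muscle markers -0.39, polyamine genes -0.35 (Btg2 higher), glycolysis -0.30 (Ldhb higher), interferon genes -0.25 and proteasome subunits -0.18. Schwann markers (0.66; Prx), glucocorticoid-responsive genes (0.31), podocyte genes (0.27), TGF-beta signalling (0.26), pericytes (0.24), fatty acid oxidation (0.20; Acot1), endothelial markers (0.18), Wnt receptors and arrestins (0.15), insulin/IGF signalling (0.11) and clock genes (0.10) had outlying medians above 0. Mhrt, Rpph1, Myl2, Myh6, Myl3 and Sv2b completed the 10 highest, Rpph1 with 222 counts against 0, at least 54.4-fold. Ms4a4c, Ly6c2, Fyb, Tlr13, C3ar1 and Tph1 completed the 10 lowest. edgeR's quasi-likelihood test called 0 of 15482 genes, with 48 at an unadjusted p under 0.05, and DESeq2 and limma-voom called 0. By size 234 genes were higher and 74 lower, against simulated means of 1548 and 1422.

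The difference between the DKK1 effects in the libraries labelled knockout and in wild type was tested as an interaction. For Fbxo32 the 2 DKK1 effects differed by a log2 of 1.72, mostly because it was lower under DKK1 in wild type. It was at 93.4 CPM in wild type DKK1 against 346 and 216 CPM in the wild type PBS libraries. In the libraries labelled knockout it was at 384 CPM under DKK1 and 341 CPM under PBS. Members with lower DKK1 effects in the libraries labelled knockout were 3 of 14 Schwann genes (median -1.60, -2.71 and -0.48; Pmp2), 3 of 24 TGF-beta genes (-0.26, -0.91 and -0.07, not outlying; Id1, Smad7) and 2 of 15 heat shock genes (-0.63, -1.25 and -0.23; Dnaja1, Hsp90aa1), with the growth factor gene Igf1 lower by a log2 of -2.55. Fos and Egr1 had higher ones, by 2.67 and 2.01 (2 of 23 immediate early genes higher, 1 lower; 0.58, 0.15 and 0.72). Slow fibre genes differed for 4 of 16 (1.61), yet the sign of that median depended on the wild type library, at -0.67 with library 1 and 3.62 with library 2. The 10 highest included Habp2, Myh7, Mhrt, Tnnc1, Tnnt1 and S100a9 with Rpph1, Rmrp, Lars2 and Rn45s, and the 10 lowest were H2-Q10, Pmp2, Duxbl2, Oas1a, Gabrb2, Rrad, Nr4a3, Cdh2, Rab6b and Ms4a4c.

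Lists whose median was below 0 with both wild type libraries were collecting duct (-1.54, -1.12 and -1.49; Aqp4), cell cycle (-1.36, -2.09 and -0.74), pericyte (-1.19, -1.76 and -0.26; Rgs5), matrix (-1.08, -1.90 and -0.24; Col15a1), and endothelial genes (-0.94, -1.12 and -0.61; Kdr). Others were kidney injury (-0.63, -1.06 and -0.06; Sox9 higher), lipid synthesis (-0.56, -1.10 and -0.18), podocyte (-0.54, -0.98 and -0.15), Wnt receptor and arrestin (-0.24, -0.36 and -0.10), fibroblast (-0.23, -0.45 and -0.09), polyamine (-0.21, -0.12 and -0.03; Gadd45g higher) and insulin/IGF genes (-0.15, -0.11 and -0.01). Skeletal muscle markers were above 0 (0.71, 1.07 and 0.36). Tendon genes went both ways (-0.16, 0.20 and -0.43; Comp and Scx higher, Cilp and Tnmd lower). The sign differed between the wild type libraries for 10 of 28 lists, which besides slow fibre and tendon genes were the fast fibre, denervation, fatty acid oxidation (Acot1), ribosomal, proximal tubule (Gatm), adipocyte (Lep), macrophage and skin lists. edgeR's quasi-likelihood test called 0 of 15482 genes, with 44 at an unadjusted p under 0.05 and a smallest adjusted p of 0.826, while DESeq2 called 3 higher, Rmrp, Rpph1 and Lars2, and limma-voom 0. By size 96 genes differed upward and 208 downward, 325 and 339 without wild type library 1 and 1067 and 1998 without library 2.

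**Figure D3:**
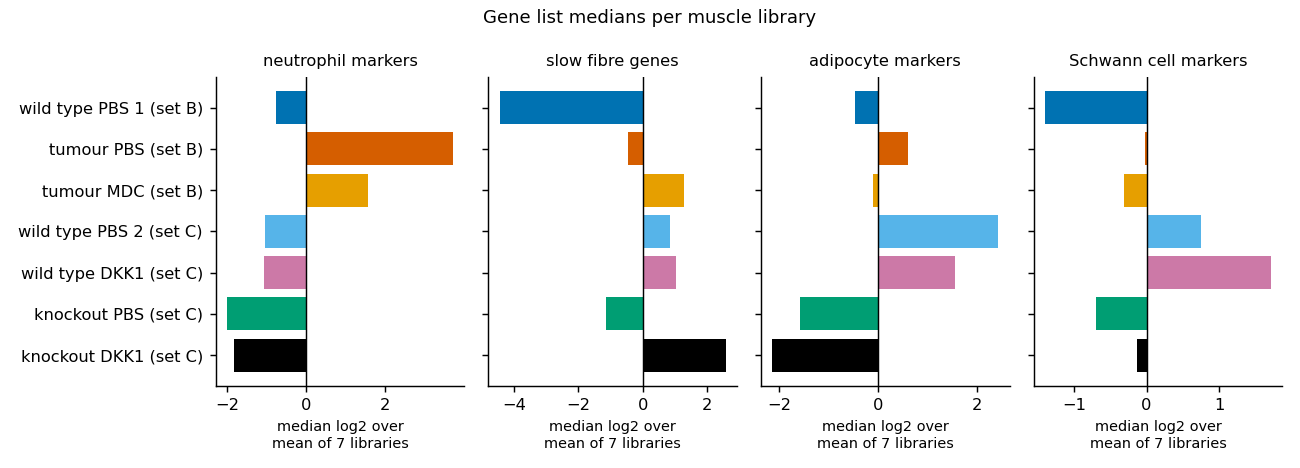
Median log2 CPM of 4 gene lists in each of the 7 muscle libraries, relative to the mean of the 7, as bars. Neutrophil markers are highest in tumour PBS (median 4.59 above wild type), slow fibre genes run from -4.44 in wild type library 1 to 2.59 in the library labelled knockout DKK1, and adipocyte markers are lowest in the libraries labelled knockout.

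The kidney comparison asks what the tumour changes in an organ other than muscle. The tumour library had more acute phase, injury and fat transcript and a lower median for proximal tubule genes. Spp1 (chromosome 5, 104435118 to 104441050) was at 19456 CPM against 760 CPM, a ratio of 25.6 (95% interval 25.3 to 25.9). Lcn2, a marker of tubular injury, was at 77.3 CPM against 2.74 CPM, a ratio of 28.2 (23.4 to 34.2), and Hp, which binds free haemoglobin, at 132 CPM against 4.42 CPM (29.9; 25.9 to 34.8). Kap, an androgen-driven protein of the proximal tubule (chromosome 6, 133849851 to 133853762), was at 2683 CPM against 23801 CPM, 8.87-fold lower (8.82 to 8.92). Inmt, an indolamine methyltransferase, was at 45.6 CPM against 975 CPM and Odc1, the polyamine synthesis enzyme, at 202 CPM against 891 CPM.

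IL-6/STAT3 and acute phase genes were at least 2-fold higher for 14 of 25 members (median log2 1.59), kidney injury genes for 13 of 28 (1.08), adipocyte markers for 12 of 16 (2.39), immediate early genes for 9 of 21 (0.92) and glucocorticoid-responsive genes for 8 of 18 (0.97). The adipokine gene Cfd was at 708 CPM against 39.2 CPM and Cidec at 164 CPM against 11.5 CPM. Whether fat in the tumour kidney piece carried part of the other lists was not tested. Zbtb16, a glucocorticoid-induced repressor (chromosome 9, 48654297 to 48836222), was at 25.3 CPM against 1.06 CPM and the salt-transport kinase Sgk1 at 230 CPM against 48.4 CPM. Nr4a3 was at 10.6 CPM against 0.662 CPM and Fos at 6.06 CPM against 1.96 CPM. Proximal tubule genes were lower for 10 of 33 members and higher for 2 (-0.58), with the amino acid carrier Slc7a13 at 208 CPM against 1236 CPM and, in the other direction, the vitamin D hydroxylase Cyp27b1 at 41.9 CPM against 8.77 CPM and the lactate carrier Slc5a12 at 1820 CPM against 732 CPM. The lipase inhibitor Angptl4 was at 135 CPM against 30.9 CPM (fatty acid oxidation, 6 of 32, 0.34). Collecting duct genes were higher for 5 of 19 (0.62), with the water channel Aqp2 at 1116 CPM against 430 CPM and the urea carrier Slc14a2 at 106 CPM against 14.8 CPM.

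Immune transcript went both ways. S100a8 had 181 counts against 3, a ratio of 57.3 (19.3 to 280), and neutrophil markers were higher for 3 of 13 (3.54). Lymphocyte markers were lower for 2 of 13 (-1.44), with the antibody-joining Jchain at 2.40 CPM against 10.1 CPM and the leukocyte phosphatase Ptprc at 4.28 CPM against 9.99 CPM. Interferon response genes were lower for 7 of 32 and higher for 2 (-0.49; Iigp1 and Gbp4 lower, Ifi27l2a and Gbp7 higher). Among macrophage markers the antigen-presenting Cd74 and H2-Aa were lower, 770 CPM against 3236 CPM and 33.8 CPM against 118 CPM, and Plac8 and Itgam higher (2 of 26 higher, 4 lower; -0.23). Clock genes split, with the repressors Cry1 and Nfil3 at 22.1 and 26.8 CPM against 2.39 and 5.36 CPM and the daytime outputs Dbp and Nr1d1 at 61.6 and 26.4 CPM against 227 and 95 CPM (5 of 20 higher, 3 lower; -0.08).

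Lists with further members higher were lipid synthesis (7 of 25, 2 lower, 0.41; Thrsp, Acacb), atrophy and FoxO targets (5 of 19, 1 lower, 0.33; Cebpd, Ddit4), heat shock (5 of 15, 0.29; Cryab, Hspa1b), loop of Henle (5 of 20, 0.32; Ptger3, Trpv5), ATF4 targets (4 of 20, 1 lower, 0.50; Asns, Psat1), iron and NRF2 (4 of 22, 0.33; Ptgs2, Mt2), glycolysis (4 of 24, 0.09; Hk2, Fbp2), skin (4 of 11, 0.50; Krt5, Krt14), p53 targets (3 of 22, 0.25; Cdkn1a, Pmaip1), liver (3 of 14, 0.26; Serpina1a, Trf), erythroid (3 of 7, 0.16; Hba-a1, Hba-a2), insulin/IGF (3 of 20, 1 lower, 0.17; Igfbp3 lower), TGF-beta (3 of 22, 1 lower, 0.04; Fst, Gdf11), Wnt targets (2 of 22, 1 lower, -0.06; Sfrp5, Myc), denervation (2 of 11, 0.80; Chrnb1) and Schwann genes (2 of 13, 0.82; Mbp, Cnp). The erythroid count and median leave out the beta-globin genes Hbb-b1 and Hbb-b2, which were higher at log2 ratios of 2.04 and 1.89. Matrix genes were lower for 3 of 30 with Postn higher (-0.13; Col5a1, Col5a2). Outlying medians were also found for polyamine (0.29), endothelial (0.26; Ly6c1) and ribosomal genes (0.25), and for pericytes (-0.38; Kcnj8), skeletal muscle markers (-0.39), fast fibre genes (-0.29) and proteasome subunits (-0.26), and 12 lists met no criterion. The 10 highest genes were Itih4, Agt, Serpina10, Meox2, Htr3a, Adgra1, S100a8, Hp, Apcs and Cfi, at log2 ratios of 4.80 to 6.08, and beside Inmt the 10 lowest held Cntnap5a, with 0 counts and at least 35.5-fold lower, Col19a1, Slco1a1, Aqp8, Hapln1, Tbx10, Cxcr6, Cyp2d12 and Ces2b. Arrb1 was at 38.4 CPM against 70.7 CPM, Lrp6 at 148 CPM against 187 CPM and Axin2 at 1.91 CPM against 1.87 CPM. By size 731 genes were higher and 515 lower, of 12878 with 100 or more counts. The comparison is of 2 libraries, so the intervals cover counting error and not differences between animals.

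**Figure D4:**
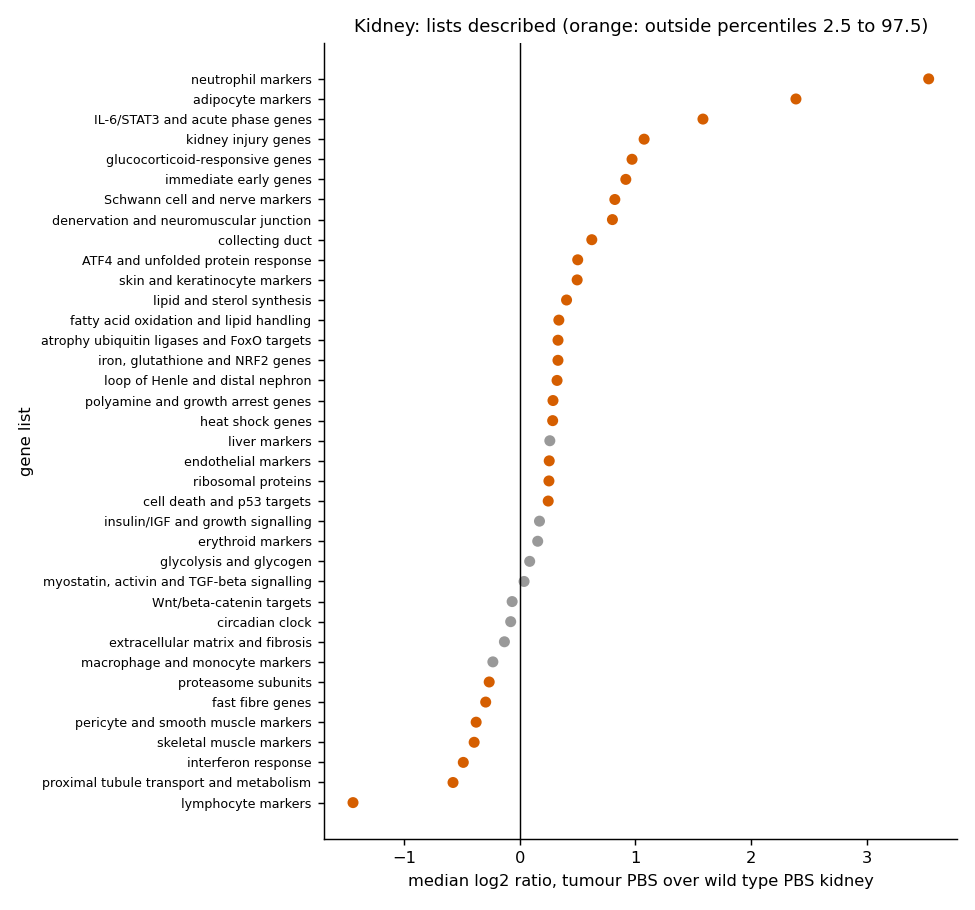
Median log2 ratio of tumour PBS over wild type PBS kidney for each of the 37 gene lists described, 1 point per list, with orange points for medians outside the central 95% of matched random lists. Neutrophil (3.54) and adipocyte markers (2.39) lie highest and lymphocyte markers (-1.44) lowest.

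Tumour changes in kidney and muscle correlated weakly, at r = 0.150 across 14574 genes, which are not independent replicates. The value was 0.20 with wild type muscle library 1 alone and 0.0312 with library 2 alone. By size 31 genes were higher in both tissues, where independent lists would give 5.91, and 2 were lower in both, where they would give 1.40. These expected values count all 14574 genes, also those with too few counts to pass the size rule, and so lie too low. Those higher in both included the cytokine-response genes Socs3 (log2 1.24 in muscle and 2.25 in kidney), Osmr (1.47 and 1.59) and Cebpd (1.90 and 1.95), the copper carrier Cp (1.52 and 2.1) and the lipocalins Lcn2 (4.16 and 4.79) and Apod (1.97 and 3.0). Mt1, Mt2, S100a8, S100a9, Cxcl13, the globin genes and Mup2, Mup9, Mup10 and Mup16 were also among them, with related genes counted singly. Cyp26b1, which breaks down retinoic acid, was lower in both (-2.39 and -1.68).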

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

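The tests of blood, of library sets, of fibre type and of mixed labels were chosen after the results were seen, and the tests for genes near Arrb1 and Arrb2 were chosen before. Among lists described by name in both tissues, 3 had a median change with the tumour in kidney opposite in sign to that against each wild type library in muscle. These differences were not tested, and lists outside that rule could also differ in sign. Iron, glutathione and NRF2 genes had a median log2 change of 0.33 in kidney and -0.10 and -0.11 against the 2 wild type libraries in muscle, where the median was not outlying (percentile 33.6) and the 3 members past the size rule were higher, as 4 were in kidney. Lymphocyte markers had a median of -1.44 in kidney and 0.95 and 1.20 in muscle. Liver markers had a median of 0.26 in kidney and -0.49 and -1.20 in muscle.

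Neutrophil markers were higher in tumour PBS muscle, with a median log2 change of 4.59, and lower in the MDC library. More blood of unchanged make-up would raise neutrophil and erythroid markers alike, but the neutrophil median exceeded the erythroid one by 2.54 or more, or by 1.97 or more with members at 0 put at the bound that 3 counts give. A difference between library sets would leave the tumour library level with the wild type library of its own set, where the median was 4.52 (4.41 at that bound). Less blood in the MDC piece would lower erythroid markers, whose median against tumour PBS was 0.26 while that of neutrophil markers was -2.63. A change in blood make-up, neutrophils in the tissue and differences between single animals remain open, and a neutrophil response to the tumour may be 1 candidate explanation that these libraries do not test.

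Slow fibre genes lay far apart between muscle libraries. DKK1, MDC or the tumour as the sole cause does not account for the range of 5.28 log2 units among the 3 libraries given PBS without a tumour. Heart tissue would bring Myl7, Nppa, Tnni3 and Nkx2-5, which together reached at most 0.614% of the CPM of Myh7 in the 4 libraries with a slow fibre median above 0. Another muscle, or another part of it, could give such differences, but the relation between slow fibre genes and the fast myosin Myh4 over the 7 libraries was weak (r = -0.505, exact permutation p = 0.246; rho = -0.321, exact permutation p = 0.498). Without the 2 libraries farthest from the median, wild type library 1 and the library labelled knockout PBS, r was 0.138, so the relation rests on those libraries and the explanation stays open.

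Arrb1 and Arrb2 were not lower in the libraries labelled knockout. Pairing the 4 libraries of set C by label set 87 genes 4-fold or more apart in all cross pairs, against 2 and 5 for the other pairings, which argues against an exchange of 1 library between the pairs unless something other than genotype pairs them. These genes leave an exchange of both labels open, since the 3 muscle libraries of set B lay nearer the wild type pair for 15 of the 87 genes (Rpl29 and Trim12a among them), nearer the knockout pair for 25 (Habp2 and Plet1os among them) and were split for 47. Such an exchange would not account for the arrestin counts, since neither pair was 2-fold below the other. Arrb1 was at 20.3 and 22.1 CPM in the set C wild type pair and 20.5 and 28.2 CPM in the pair labelled knockout. Arrb2 was at 7.85 and 8.32 CPM against 9.61 and 7.98 CPM. A deleted segment that leaves most of the transcript could come with flanking sequence of another strain, and with Trim12a and Rpl29 left out by design and 3 genes without coordinates, 6.10% of the genes apart lay within 20 Mb of Arrb1 against 1.77% of genes tested (5 of 82, exact binomial p = 0.0153), and 3.66% against 3.61% near Arrb2 (3 of 82, p = 0.572, exact binomial). The Arrb1 value met the bound written before, and a stricter bound was chosen after the value was seen, because 3 of the 5 genes (Fah, Pde3b and Plin1) were lower, as were all but 16 of the 82 genes, and Trim30d lies beside Trim12a, which is itself higher in both libraries labelled knockout and 4.69 Mb from Arrb1. Among 15 genes higher in those libraries and away from Trim12a, 1 lay near Arrb1 (exact binomial p = 0.235). So few genes cannot decide whether the share near Arrb1 holds, and the tests leave both loci open.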

How the results depend on the processing

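The leave-out counts of genes and lists, DESeq2 scaling of those counts, library sizes without 4 noncoding or ribosomal-sequence genes (Rn45s, Rmrp, Rpph1 and Lars2), the MDC share by the size rule and the kidney and muscle correlation with wild type library 2 alone were chosen after seeing the data. edgeR's quasi-likelihood test called 0 genes in all 7 muscle comparisons under DESeq2 size factors, no filter, a mean of 50 counts, 9 libraries in the fit and robust empirical Bayes, as did limma-voom, beside 38 to 231 genes at an unadjusted p under 0.05 in edgeR's test. DESeq2 called 12 genes for the tumour, 11 for MDC against wild type, 4 for DKK1, 19 for knockout and 3 for the interaction, and 0 for the other comparisons; the cause was not tested. The planned share of tumour genes called by edgeR could not be computed with 0 called, and over genes called by DESeq2, with identical-count copies entered once, it was 60.0% (6 of 10). Leaving out either wild type library left fewer libraries to pass the size rule. Counts of genes higher and lower then ranged from 918 to 938 and 260 to 821 for the tumour, 343 to 1229 and 240 to 1249 for MDC against wild type, 342 to 2442 and 124 to 1280 for DKK1, 331 to 854 and 701 to 718 for knockout and 325 to 1067 and 339 to 1998 for the interaction. Lists with 3 members or 20% past the rule ranged from 36 to 38, 24 to 39, 15 to 42, 26 to 32 and 19 to 42 in that order. With both wild type libraries they numbered 7, 9, 10, 2 and 6. With no residual degree of freedom these are values with no test. In kidney a minimum of 20 counts gave 1130 higher and 916 lower and one of 500 counts 427 and 302. In the wild type pair total counts gave 2636 and 546, 20 counts gave 2486 higher and 500 counts 636 and 838, a stricter minimum leaving fewer genes by construction. The tumour and DKK1 correlation was 0.108 within own sets and 0.108 for a mean of 50 counts. The kidney and muscle correlation was 0.20 and 0.0312 with wild type library 1 or 2 alone and 0.186 for a mean of 50 counts, and the cause was not tested. All 226 list medians and 467 named gene values stayed within their spread under DESeq2 size factors. A prior count of 0.5 moved 2 of 37 kidney list medians beyond their spread, neutrophil markers to 4.46 and lymphocyte markers to -1.65. Without wild type library 1, 13 of 189 list medians moved beyond their spread and 34 took the other sign (largest shift 2.80). Without library 2 these values were 14, 16 and 2.96. The 189 include 28 for MDC against tumour PBS and 32 for DKK1 in the libraries labelled knockout, which use no wild type library. For the rest the spread comes from the difference between the 2 wild type libraries, so few moved medians say little. Of 362 named gene values, 8 and 13 took the other sign, with largest shifts of 3.75 and 3.73. Only 0 and 2 moved beyond their spread, which carries no information for changes against wild type. There the spread comes from the difference between the 2 wild type libraries and exceeds, by construction, the shift from leaving 1 out.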

Other observations

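All genes in this part were chosen after their values were seen. Genes of fat cells, among them Adipoq, Cfd, Lep and Plin1, were lower in both libraries labelled knockout than in both wild type libraries of set C. Adipoq, the fat hormone adiponectin, was at 4.70 and 3.40 CPM in the libraries labelled knockout PBS and knockout DKK1 against 109 and 79.8 CPM in wild type PBS and DKK1. In wild type PBS library 1, of set B, Adipoq was at only 13.4 CPM. Rpl29 went the other way in set C, at 235 and 268 CPM in the libraries labelled knockout against 3.19 and 3.81 CPM in wild type PBS and DKK1. The cytokine feedback gene Cish was at 55.9 CPM in wild type DKK1 and 33.8 and 32.2 CPM in the libraries labelled knockout, beside 7.29 CPM in wild type PBS of the same set and 103 CPM in tumour PBS.

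Wild type muscle library 1 differed from the other 6 muscle libraries in interferon-induced GTPase genes. Igtp was at 503 CPM and Iigp1 at 499 CPM there, against 27.0 and 37.2 CPM or less in the others. The same library held more of 3 kidney transcripts than any other muscle library, with Kap at 52.6 CPM, Umod, the main protein of urine, at 11.3 CPM and the inositol oxygenase gene Miox at 7.87 CPM, beside 15.6, 2.27 and 1.5 CPM or less in the others.

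Some genes followed set letters. H2-Ea-ps, annotated as a polymorphic pseudogene, was at 174 and 89.0 CPM in the kidney pair and from 9.87 to 18.9 CPM in the 3 muscle libraries of set B, with 2 counts or fewer in each library of set C. Gbp2b was at 13.2 CPM or more in sets A and B and had 5 counts or fewer in each library of set C. The 2 wild type PBS muscle libraries lie on either side of these differences, so their mean and SD include them. Whether the sets differ in mouse strain was not tested. The amylase gene Amy2a5 had 497 counts in tumour PBS muscle, 40 in MDC muscle and 0 in the other 7 libraries.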
